A study of Homo sapiens with 12 samples.

How the data were processed

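Chromatin accessibility was measured by Omni-ATAC, in which the Tn5 transposase cuts open chromatin and inserts sequencing adapters, in 12 libraries of MV4-11 cells, 6 from vehicle wells and 6 from menin inhibitor wells. Per the file headers, the authors' count table was made with featureCounts 2.0.1 in paired, unstranded mode. A fragment could count for several intervals and had to overlap an interval by a share of at least 0.2. The deposited values are raw fragment counts over 272408 consensus intervals of the whole series, with no normalization. BWA, MACS2, bedtools and the build GRCh38 are named without versions in the submitters' processing notes. The parameters of alignment, duplicate removal and peak calling, and whether cut positions were shifted for the transposase, are not given in the sources used here. The authors deposited 1 broad peak file per library, not pooled, and its 9th column holds each peak's -log10 q-value as the peak caller gave it, never below 1. These scores were used only to filter peaks within a library.

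Library totals over the intervals ranged from 12616227 to 36740944 counts, and 188170 intervals passed edgeR's filterByExpr at its default minimum count of 10. Sequencing depth outside the intervals is not given in the sources used here. The wells are named by group and replicate number from the titles. All columns of per-sample values were used.

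Pairs of libraries were compared before averaging by a chi-square test of their counts over the 77679 intervals with a mean of at least 50 counts. In 3 pairs the chi-square per interval was 0.978, 0.981 and 1.00, at or near the sampling noise of counts. Each such pair was entered as 1 unit into means and standard deviations, which leaves n = 4 for vehicle and n = 5 for inhibitor. The models kept all 12 libraries.

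Accessibility per interval was tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, the robust quasi-likelihood F-test with group as the only term, and Benjamini-Hochberg adjustment over the tested intervals. The threshold was an adjusted p of 0.05, and all tests were two-sided. Standard errors of log2 fold changes were taken as the size of the log2 fold change divided by the square root of the F statistic. CPM values are TMM-scaled with a prior count of 2. The principal components used the 20000 most variable intervals on the log2 CPM scale.

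The reference used here was a gene table of GRCh38.p14 with the start and end of 20033 protein-coding genes on the build that the files use. It gives neither strand nor exons, so transcription start sites could not be placed. The planned promoter sums were replaced by gene ends, which are the intervals overlapping 1 kb either side of either end of a gene. Gene-end sums could be formed for 16081 genes, of which 5096 shared an interval with another gene, and 15280 were tested with the same edgeR model. The TMM factors of this fit were computed over gene ends, with interval totals as library sizes, so a gene-end value is relative to the other gene ends. A locus is the gene span with 10 kb on both sides. Intervals were placed once each as at a gene end, within a gene or outside genes, and their shares were compared by Fisher's exact test against the other tested intervals. The planned motif search and corrections for GC content need the genome sequence and were not run.

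The 20 gene lists were fixed before the data were examined and hold 395 distinct genes, all matched, 1 of them through an older symbol. They cover menin and KMT2A fusion targets, members of the menin, KMT2A and elongation complexes, monocyte and macrophage genes, granulocyte genes, stem and progenitor genes, myeloid transcription factors, MHC genes, interferon response genes, AP-1 and immediate early genes, cell cycle genes, cell cycle inhibitors, apoptosis regulators, FLT3 and cytokine receptor signalling, lysosomal genes, homeobox genes outside the HOXA cluster, markers of T and NK cells, B cells, erythroid and megakaryocyte cells, and epithelial cells and fibroblasts, and housekeeping genes. Lists were tested with camera (limma 3.58.1) on voom values at a preset inter-gene correlation of 0.01, adjusted over the 20 lists, and again with the correlation estimated per list and with fry. Some genes stand in more than 1 list.

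Named intervals were the 8 largest rises and 8 largest falls among intervals past the threshold with a mean of at least 50 counts, complete separation of the groups, and a protein-coding gene within 10 kb, 1 per gene. The distance was taken on both sides of the gene, since the strand was unknown. Named genes were up to 2 risers and 2 fallers per list with the smallest p, and 16 genes named in every case. Of the genes this rule names, 3 are not reported here.

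Peak number, covered length and median width per library, the share of counts in the strongest 10% of intervals, library totals and the share on unplaced contigs were compared by exact permutation tests of the difference in means over all 12 libraries, adjusted over these 6 measures. Intervals with peaks in every library of 1 group and none of the other were counted with an overlap of at least 1 bp and compared with the same count in every other split of the libraries. Shares of counts per chromosome were tested by exact permutation, adjusted over 23 chromosomes.

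Accessibility between genes of a list and away from gene ends was compared by the median over loci, each locus entering with the median of its intervals outside gene ends, against 10000 draws of random loci matched on the number of intervals and mean abundance. Loci with fewer than 5 such intervals were left out.

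The alternatives tried were DESeq2 1.42.0, RLE factors, library totals without composition factors, loess offsets against abundance (span 0.3), no filter, a mean of at least 50 counts, the replicate number as a block, 1 surrogate variable (sva 3.50.0), a 2-fold threshold, windows of 500 bp and 2.5 kb, locus sums, intervals of 1 gene only, stricter peaks (-log10 q of at least 5), other overlap rules, and each library left out in turn. Merging the near-identical libraries, and using only the gene end with more counts, were added after the data had been seen.

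The steps were tested on simulated data with 200 changed features drawn on the real means and library sizes. Rises and falls were nearly balanced, and no trend with abundance was simulated. The simulations therefore do not test the scaling, or recovery where as many features change as were called here. For intervals, 33 of 67 changes of 1.5-fold, 56 of 67 of 2-fold and 64 of 66 of 4-fold were recovered, with 8 false calls among 161. For gene ends, 63 of 67, 66 of 67 and 66 of 66 were recovered, with 15 false calls among 210. A simulated list of 20 genes raised 1.5-fold was recovered, and of the 100 lists simulated in all 1 other was called. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.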

Results

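MV4-11 is an established human acute myeloid leukaemia line that carries a fusion of KMT2A (MLL) with AFF1 and a FLT3 mutation. The labels give its source as peripheral blood and its cell type as macrophage. Menin, the product of MEN1, is a scaffold protein that binds KMT2A and its fusion proteins at chromatin, and menin inhibitors occupy the pocket that holds KMT2A. The series asked how menin inhibition alters open chromatin in this line. Cells from an expanded culture were seeded in wells, kept for 48 h with the solvent DMSO or with an inhibitor, and assayed by Omni-ATAC, which reads accessible DNA by transposase insertion.

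The labels disagree about the compound. The sample titles and treatment protocol name SNDX-5613 at 0.2 µM, and the sample characteristics and series design name MI-463 at 1 µM. Both are menin inhibitors, so the treated group is called menin inhibitor here, and no statement is made about which compound or dose was used. There were 6 libraries per group. Nothing in the labels says that the wells came from separate cultures, so p-values of tests between libraries measure only the spread between wells, which may be technical.

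The vehicle libraries held 16459123 to 20993597 counts in 272408 consensus intervals, and the inhibitor libraries 12616227 to 36740944. By the chi-square test per interval, vehicle libraries 3 and 4, vehicle libraries 5 and 6, and inhibitor libraries 2 and 3 differed by no more than sampling noise. They are called near-identical in that sense only. Chromosome 19 held 8.69% and 8.80% of counts in inhibitor 2 and 3, and 8.23% and 8.15% in vehicle 5 and 6. The correlation of vehicle 3 and 4 was 0.974, the median within vehicle. Each pair was counted as 1 sample in every mean ± SD, giving n = 4 for vehicle and n = 5 for inhibitor, while the edgeR models used all 12 libraries.

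The groups separated along the first principal component, which took 72.0% of the variance. Pearson correlations of log2 CPM across intervals were 0.962 to 0.982 within groups and 0.907 to 0.935 between them, intervals not being independent replicates. The inhibitor libraries had more of their counts in the strongest 10% of intervals, 63.5% ± 0.772 (SD, n = 5) against 59.0% ± 1.47 (SD, n = 4) in vehicle. This share was higher in every inhibitor library than in any vehicle library (exact permutation p = 0.00216, adjusted p = 0.0130). Library totals themselves did not pass the test (exact permutation p = 0.597), and 2 libraries, vehicle 2 and inhibitor 5, stood apart from their groups.

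**Figure D1:**
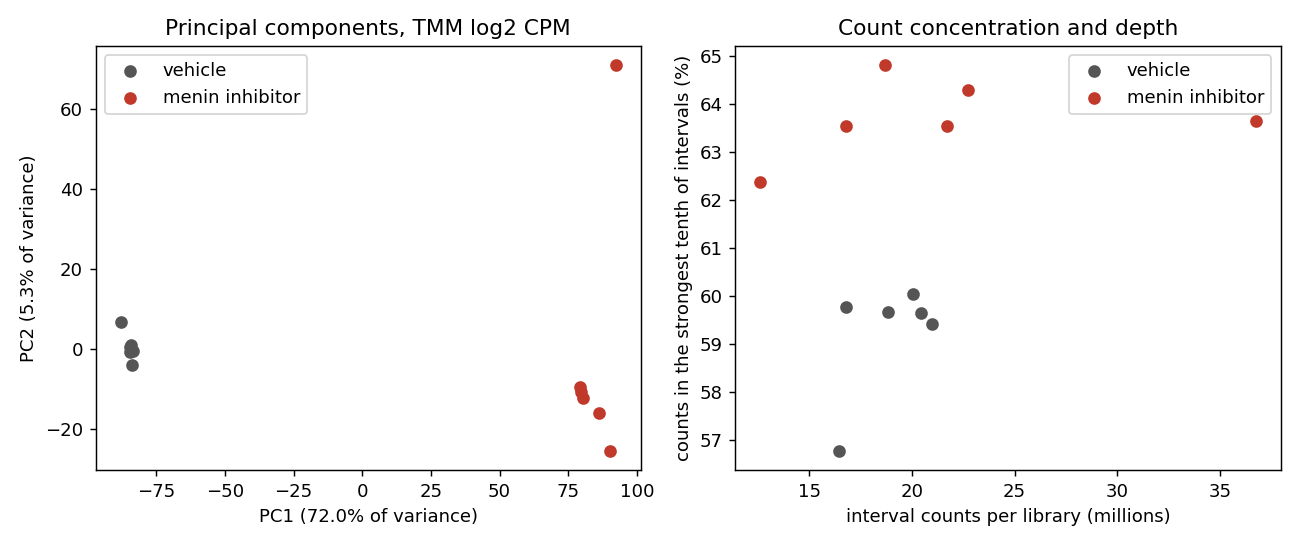
Left, the first and second principal components of log2 CPM, 1 point per library, in grey for vehicle and red for menin inhibitor; the second took 5.3% of the variance and sets inhibitor library 5 apart at 70.9. Right, the total counts of each library against the percentage of counts in the strongest 10% of intervals, which ran from 62.4% to 64.8% with inhibitor and from 56.8% to 60.0% with vehicle.

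Rises and falls were ranked among changed intervals with a mean of at least 50 counts, separated groups and a gene within 10 kb. The 8 largest rises included some beside chemokine and immediate early genes. An interval next to the chemokine gene CCL2 (chromosome 17, 34257257 to 34257698, at a gene end) went from 0.320 ± 0.0861 CPM (SD, n = 4) to 4.43 ± 0.923 CPM (SD, n = 5), a log2 fold change of 4.30 ± 0.19 (SE). An interval over CXCL8, which encodes the neutrophil chemoattractant interleukin 8 (chromosome 4, 73742199 to 73745165), went from 1.78 ± 0.424 to 26.2 ± 2.56 CPM (log2 fold change 4.09 ± 0.09). Beside SGK1, a serum- and glucocorticoid-induced kinase (chromosome 6, 134167689 to 134169241), the log2 fold change was 3.25 ± 0.11. It was 2.85 ± 0.14 beside the immediate early gene EGR3 (chromosome 8, 22685487 to 22687390) and 2.73 ± 0.10 beside LYZ, the lysozyme gene of monocytes and granulocytes, and YEATS4 (chromosome 12, 69354424 to 69355215). The interval at BTG2, an antiproliferative gene (chromosome 1, 203308587 to 203310589), rose by 2.58 ± 0.15, and intervals within NMNAT2 (chromosome 1, 183363997 to 183364341) and TMEM233 (chromosome 12, 119603079 to 119604161) by 3.32 ± 0.15 and 2.84 ± 0.15. Adjusted p-values of these 8 intervals ran from 1.76e-49 to 3.36e-08 in edgeR.

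Under the same rule, the 8 largest falls all lay within genes and more than 1 kb from a gene end. Of all 11855 falls of at least 2-fold, 6001 lay outside genes and 5524 within. The interval within PXK (chromosome 3, 58348211 to 58348482) went from 9.04 ± 0.339 CPM (SD, n = 4) to 0.854 ± 0.194 CPM (SD, n = 5), a log2 fold change of -3.64 ± 0.12 (SE). The interval within KCNN2, a potassium channel gene (chromosome 5, 114438330 to 114440667), went from 15.7 ± 0.760 to 2.27 ± 0.216 CPM (-2.88 ± 0.08). An interval within REEP3 and less than 10 kb from JMJD1C (chromosome 10, 63523160 to 63524801) went from 11.0 ± 0.400 to 1.65 ± 0.193 CPM (-2.84 ± 0.09). JMJD1C ends at 63521890, so this interval lies less than 2.5 kb from a gene end. The other falls were within ILDR2 (chromosome 1, 166906082 to 166906369, -3.09 ± 0.15), UNC5D (chromosome 8, 35367684 to 35367968, -3.06 ± 0.14), PHACTR1 (chromosome 6, 12735056 to 12735609, -3.00 ± 0.12), PHF10 (chromosome 6, 169714055 to 169715120, -2.93 ± 0.13) and METTL15 (chromosome 11, 28384255 to 28384770, -2.92 ± 0.13). Adjusted p-values of these 8 intervals ran from 2.74e-50 to 5.97e-32. Whether the intervals are exonic or intronic was not analysed here.

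Over the whole set, 51407 of 188170 tested intervals were higher and 48513 lower in inhibitor libraries past an adjusted p of 0.05 (edgeR). Among the large changes 3970 intervals were at least 2-fold higher and 11855 at least 2-fold lower, or 5610 and 8843 with loess offsets. With library totals in place of TMM factors, 35879 were higher and 62603 lower, the share of higher calls going from 51.4% to 36.4% and the median log2 fold change from 0.01 to -0.10. Strong intervals tended to rise and weak ones to fall. Loess offsets that remove this trend gave 47649 higher and 46525 lower intervals and kept 82624 of the calls in the same direction.

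Rises were more frequent at gene ends than elsewhere, and falls less frequent. Of the intervals that rose, 19.98% lay at a gene end, against 5.91% of the other tested intervals (odds ratio 3.98, 95% interval 3.86 to 4.10, Fisher's exact test). Of those that fell, 4.63% lay at a gene end, against 11.5% of the others (odds ratio 0.373, 0.356 to 0.390). Intervals at gene ends had a median mean count of 207.75, against 34.75 within and 33.5 outside genes, and with loess offsets the odds ratios were 1.51 for rises and 0.591 for falls. At gene ends 10270 of 18347 intervals rose and 2246 fell, with a median log2 fold change of 0.23. Within genes 20902 rose and 22900 fell of 85452, and outside genes 20235 rose and 23367 fell of 84371. Intervals are not independent replicates, so the confidence intervals are too narrow. Changes of at least 2-fold were less frequent at gene ends in both directions, with 199 rises (odds ratio 0.483) and 330 falls (odds ratio 0.252).

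Menin and KMT2A fusion targets had more members down than up. Among the 25 tested members, 17 fell, 4 rose and 4 did not pass, with the same counts adjusted over the list alone (median log2 fold change -0.24, camera adjusted p = 4.46e-04, adjusted p = 0.0644 with an estimated correlation). With library totals 13 fell and 8 rose (median -0.11). MEIS1, a homeobox gene that acts with HOXA9 in leukaemia (chromosome 2, 66435125 to 66573869), went at its gene ends from 55.1 ± 2.83 CPM (SD, n = 4) to 32.8 ± 0.927 CPM (SD, n = 5), a log2 fold change of -0.78 ± 0.04 (SE, edgeR adjusted p = 3.54e-18). Across its locus 22 of 28 tested intervals fell and 2 rose, and the interval with the largest fall, chosen after its values were seen (chromosome 2, 66455633 to 66455917, within the gene) had a log2 fold change of -3.30 ± 0.30. HOXA10 (chromosome 7, 27170605 to 27179861) fell by 0.67 ± 0.07, HOXA9 (chromosome 7, 27162438 to 27165537) by 0.40 ± 0.04, and the progenitor transcription factor MYB (chromosome 6, 135181308 to 135219172) by 0.48 ± 0.05 on the log2 scale. Rises at gene ends included JMJD1C, a histone demethylase family gene (chromosome 10, 63167225 to 63521890), with 0.30 ± 0.05, and the protease gene ADAM10 with 0.19 ± 0.04. JMJD1C shares 1 of its 2 end intervals with another gene, and its value turned to -0.37 over intervals of 1 gene only and to -0.21 with 2.5 kb windows. The call of ADAM10 ended with the locus sum (0.039). HOXA9 and HOXA10 each share an interval with the readthrough gene HOXA10-HOXA9, and the call of HOXA9 was lost over intervals of 1 gene only (-0.11, adjusted p = 0.171) and that of HOXA10 over its stronger end only (-0.22, adjusted p = 0.0573).

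Loci of several targets held many intervals that fell. At CDK6, a cell cycle kinase gene (chromosome 7, 92604921 to 92836573), 34 of 41 intervals fell and 1 rose, while its gene ends fell by 0.24 ± 0.03 on the log2 scale. At JMJD1C 34 of 57 intervals fell and 5 rose, the locus sum giving -0.49 ± 0.03. PBX3, a cofactor of MEIS1 and HOXA9 (chromosome 9, 125747373 to 125967377), had 15 of 23 intervals lower and 3 higher. Its gene ends had a log2 fold change of -0.09 ± 0.04 (adjusted p = 0.0360), a call lost without vehicle 3 (-0.08), vehicle 4 (-0.08), inhibitor 1 (-0.07) or inhibitor 3 (-0.08) and turned to 0.04 by library totals. It was also lost without a filter (-0.08), with merged near-identical libraries (-0.08) and over intervals of 1 gene only (-0.07). FLT3, the receptor kinase mutated in this line (chromosome 13, 28003274 to 28100576), fell by 0.30 ± 0.04 at its ends, with 9 of 21 intervals lower and 0 higher. BCL2, an anti-apoptotic gene, had -0.14 ± 0.04 with 17 of 42 intervals lower and 5 higher, and MYC -0.14 ± 0.03 with 1 of 8 lower and 2 higher, both calls ending with library totals (-0.02 and -0.01) and that of MYC with the locus sum (-0.0041). MEF2C had no tested gene end, and 2 of its 16 intervals fell and 5 rose. Of the fusion partners and menin, KMT2A had 0.15 ± 0.04 (2 of 11 intervals higher, 1 lower), AFF1 -0.11 ± 0.03 (6 of 41 higher, 12 lower) and MEN1 0.08 ± 0.04, which did not pass (adjusted p = 0.0660). MEN1 did pass without vehicle 3 (0.10), vehicle 4 (0.10) or inhibitor 5 (0.08), with library totals (0.21), the replicate block (0.08), the surrogate variable (0.08), 2.5 kb windows (0.11) and the locus sum (0.15).

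**Figure D2:**
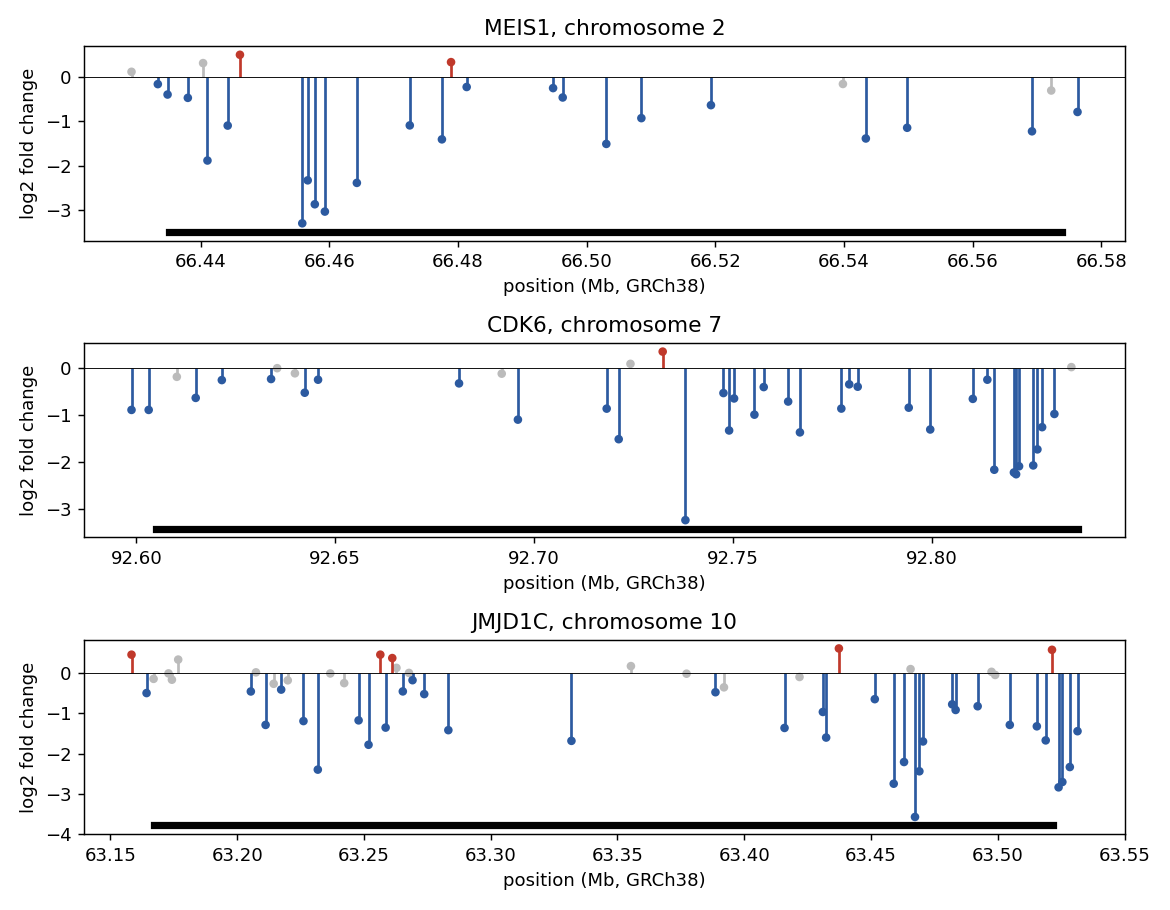
Log2 fold change, inhibitor against vehicle, of each tested interval at its position in Mb (GRCh38) across MEIS1, CDK6 and JMJD1C with 10 kb on both sides; red marks intervals that rose, blue those that fell, grey those that did not pass, and the black bar spans the gene. Of the intervals shown, 22 of 28, 34 of 41 and 34 of 57 fell.

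**Figure D3:**
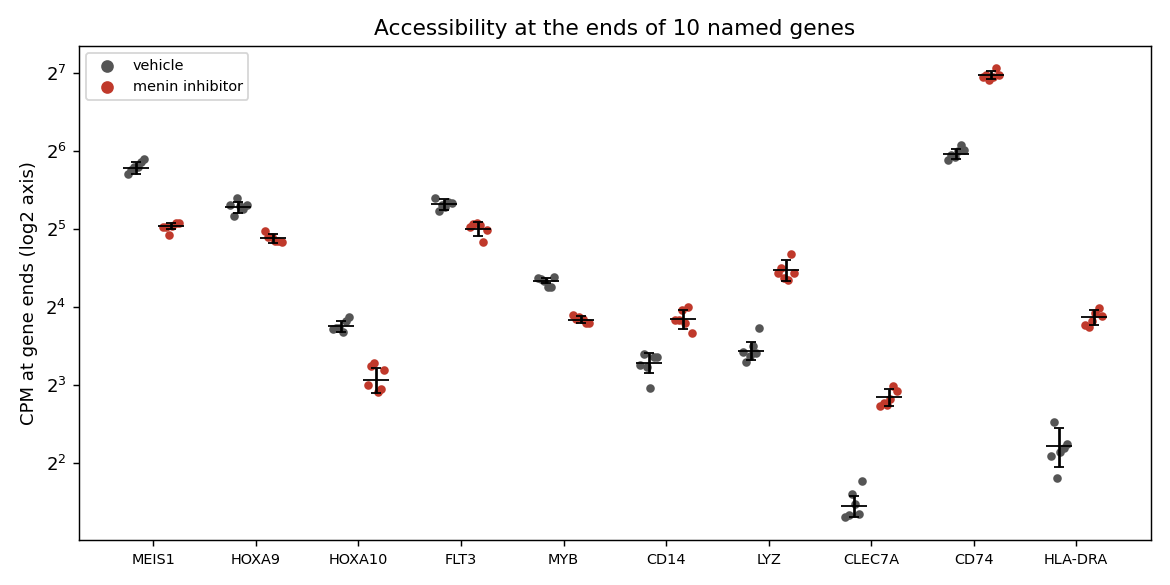
CPM at the gene ends of 10 named genes on a log2 axis, 1 point per library, in grey for vehicle and red for menin inhibitor, with horizontal bars for the mean and vertical bars for the SD (n = 4 and n = 5 after near-identical libraries were counted once). MEIS1, HOXA9, HOXA10, FLT3 and MYB are lower with inhibitor, and CD14, LYZ, CLEC7A, CD74 and HLA-DRA higher.

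Over all 15280 tested genes, 4237 gene ends were higher and 3822 lower (edgeR, adjusted p of 0.05), of which 28 rose and 312 fell at least 2-fold. These last counts were 60 and 112 with loess offsets and 19 and 94 with a mean of at least 50 counts. With library totals 7837 were higher and 2070 lower, the share of higher calls going from 52.6% to 79.1% and the median log2 fold change from 0.01 to 0.14, so every gene-end value is relative to the median gene end. Of the 20 lists, 10 passed with camera and 4 of them with an estimated correlation. Of these 4, MHC class II and antigen presentation alone passed with an estimated correlation when near-identical libraries were merged, with the replicate block, loess offsets, library totals or the locus sum.

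MHC class II and antigen presentation genes rose together, 16 of 18 past the threshold and 0 down, with the same counts adjusted over the list alone (median 0.57, camera adjusted p = 5.06e-13, adjusted p = 0.00861 with an estimated correlation). HLA-DRA, a class II alpha chain (chromosome 6, 32439887 to 32445046), went from 4.66 ± 0.800 CPM (SD, n = 4) to 14.6 ± 0.931 CPM (SD, n = 5), a log2 fold change of 1.69 ± 0.08 (SE, edgeR adjusted p = 4.04e-18). CD74, the invariant chain that escorts class II molecules (chromosome 5, 150401639 to 150412910), went from 62.3 ± 2.76 to 126 ± 4.36 CPM (0.99 ± 0.04, adjusted p = 3.59e-21), and shares an interval with TCOF1. HLA genes have near-identical copies, so fragments may be placed wrongly among them, and 5 of the 6 members outside the HLA genes rose, with a median of 0.30.

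Monocyte and macrophage genes were mixed, with 12 of 29 up, 3 down and 14 not past the threshold, and the same counts adjusted over the list alone (median 0.07, camera adjusted p = 0.0338). The adjusted p was 0.211 with an estimated correlation and 0.119 with library totals. CLEC7A, a receptor for fungal glucans (chromosome 12, 10116777 to 10130304), rose by 1.36 ± 0.09 on the log2 scale, from 2.72 ± 0.256 CPM (SD, n = 4) to 7.19 ± 0.561 CPM (SD, n = 5). LYZ rose by 1.00 ± 0.06 and CD14, the lipopolysaccharide co-receptor of monocytes (chromosome 5, 140631732 to 140633701), by 0.58 ± 0.07, with 4 of its 4 locus intervals higher. The integrin gene ITGAM went the other way at its ends (-0.27 ± 0.05; locus sum 0.0102) with 3 of 11 locus intervals higher and 1 lower, and so did LGALS3 (-0.69 ± 0.13), a call that ended with the locus sum (-0.07).

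AP-1 and immediate early genes and myeloid transcription factors, lists that share EGR1, each had more members up than down. Of 19 AP-1 and immediate early genes 14 rose and 1 fell (median 0.34, camera adjusted p = 7.01e-09, adjusted p = 0.0208 with an estimated correlation, and 0.0521 to 0.288 over the 5 settings in which MHC class II genes alone passed it). Of 24 myeloid transcription factors 14 rose and 2 fell (median 0.27, camera adjusted p = 8.42e-06, adjusted p = 0.0364 with an estimated correlation, 0.0820 to 0.298 in those settings and 0.0627 without vehicle 3). Both counts were the same adjusted over the list alone. JUN, a subunit of AP-1, had a log2 fold change of 0.64 ± 0.04, EGR1 0.61 ± 0.04 and EGR2 0.72 ± 0.03. RUNX2 fell by 1.27 ± 0.18 and the repressor GFI1 by 0.15 ± 0.04, the last call ending with library totals (-0.03). BATF3 fell by 0.18 ± 0.06, a call lost without vehicle 3 (-0.15) and with library totals (-0.06).

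Cell cycle inhibitors and apoptosis regulators each had more members up than down. Of 13 cell cycle inhibitors 7 rose and 1 fell (median 0.17, camera adjusted p = 0.00506, adjusted p = 0.0364 with an estimated correlation), led by BTG2 (1.16 ± 0.04) and the stress gene GADD45B (0.82 ± 0.03). With an estimated correlation the list had an adjusted p = 0.0741 to 0.323 in the same 5 settings, 0.0627 without vehicle 3 and 0.0565 without inhibitor 1. CDKN2A had -0.14 ± 0.03, a call that ended with library totals (-0.02). Of 17 apoptosis regulators 8 rose and 4 fell (median 0.08, camera adjusted p = 0.0375), and the adjusted p was 0.175 with an estimated correlation, 0.148 with loess offsets and 0.0501 with library totals. The members went both ways in function: PMAIP1, which promotes apoptosis, rose by 0.85 ± 0.04 and MCL1, which blocks it, by 0.73 ± 0.04. BAK1 (-0.16 ± 0.04) and CASP8 (-0.17 ± 0.05), both pro-apoptotic, fell, and both calls ended with library totals (-0.03 and -0.05), and that of BAK1 with 500 bp windows (-0.014). Counts for both lists were the same adjusted over the list alone.

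Members of the menin, KMT2A and elongation complexes had 10 up and 3 down of 22 (median 0.10, camera adjusted p = 0.0375). The adjusted p was 0.176 with an estimated correlation, 0.333 with loess offsets and 0.258 with the locus sum. KMT2C (0.33 ± 0.05) and DPY30 (0.23 ± 0.03) rose, while RBBP5 (-0.14 ± 0.04) and AFF1 fell, calls that ended with library totals (-0.01 and 0.02). With the locus sum RBBP5 turned to 0.036, and the call of AFF1 ended with the stronger gene end only (-0.075). The call of KMT2C ended with the locus sum (0.045) and that of DPY30 over intervals of 1 gene only (0.063). Housekeeping genes were not flat: 11 of 16 rose and 1 fell, or 2 adjusted over the list alone (median 0.19, camera adjusted p = 1.53e-04, adjusted p = 0.0644 with an estimated correlation). The actin gene ACTB had 0.92 ± 0.04. RPS18 had -0.08 ± 0.03 (adjusted p = 0.0466), which turned to 0.05 with library totals, 0.035 with the locus sum and 0.13 with the stronger gene end only. It was not past without a filter (-0.07), with DESeq2 (-0.085) or with merged near-identical libraries (-0.07). Its call was lost without vehicle 1, 4, 5 or 6 or inhibitor 2, 3, 4 or 6, at values from -0.08 to -0.06.

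**Figure D4:**
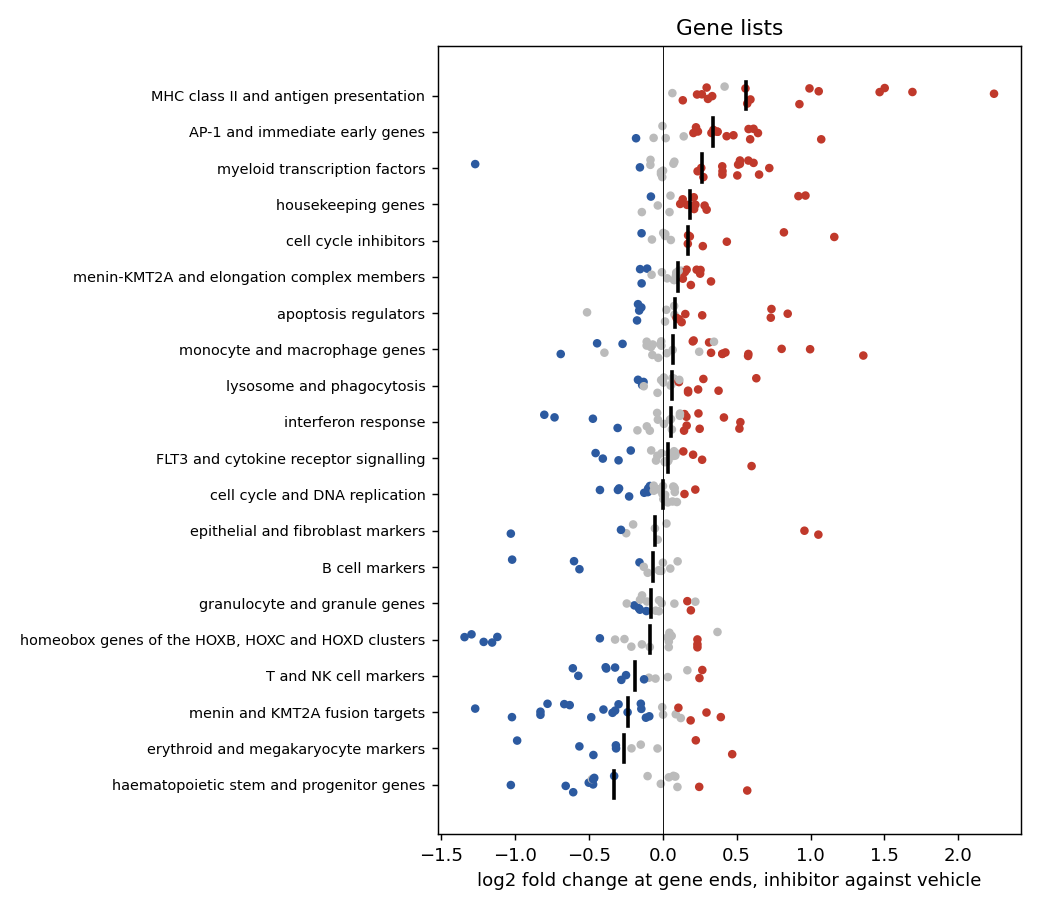
Log2 fold change at gene ends, inhibitor against vehicle, of each tested member of the 20 lists, 1 point per gene, in red where it rose, blue where it fell and grey where it did not pass; the black bar is the list's median. MHC class II and antigen presentation genes have the highest median, 0.57, and stem and progenitor genes the lowest, -0.33, a list that did not pass the test (camera adjusted p = 0.112).

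No marker list of another cell type passed upward with camera. T and NK cell markers had 8 of 14 down and 2 up (median -0.19, camera adjusted p = 0.0338). The adjusted p was 0.0724 with an estimated correlation, 0.151 with loess offsets and 0.192 with the locus sum. CD28 fell by 0.57 ± 0.07 and NKG7 by 0.32 ± 0.05, the latter turning to 0.17 with the locus sum. CD4, which monocytes also carry, rose by 0.27 ± 0.04, a call that ended over intervals of 1 gene only (0.04), and CD2 by 0.25 ± 0.09, lost without vehicle 1 (0.18) or inhibitor 6 (0.21) and with the stronger gene end only (0.19). Of 12 B cell markers 4 fell and 0 rose (median -0.064, camera adjusted p = 0.0908), among them VPREB1 (-1.02 ± 0.14) and FCER2 (-0.60 ± 0.06; locus sum 0.073). With library totals 3 fell and 2 rose (median 0.065), with loess offsets 3 fell and 1 rose, and with the locus sum 6 of 15 fell and 3 rose. Of 10 erythroid and megakaryocyte markers 5 fell, or 6 adjusted over the list alone, and 2 rose (camera adjusted p = 0.177), with ITGA2B at -0.47 ± 0.06, EPOR at -0.56 ± 0.10, KLF1 at 0.47 ± 0.07 and TFRC at 0.22 ± 0.04. With the locus sum 5 of 16 fell and 7 rose, EPOR turned to 0.10 (2.5 kb windows 0.042) and the call of TFRC ended (0.032). Of 9 epithelial and fibroblast markers 2 rose and 2 fell (camera adjusted p = 0.844), with KRT19 at 1.05 ± 0.13, CLDN4 at 0.96 ± 0.21, THY1 at -1.03 ± 0.11 and PDGFRA at -0.28 ± 0.11. The last call was lost without vehicle 5 (-0.24), inhibitor 3 (-0.24) or inhibitor 6 (-0.26), with library totals (-0.15), with loess offsets (-0.036) and with DESeq2 (-0.29). For this list the median was -0.05, the mean 0.02 and the test's direction down.

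The remaining lists did not pass with camera. With library totals falls did not outnumber rises among stem and progenitor genes (6 and 6), HOXB to HOXD genes (5 and 7) or granulocyte genes (0 and 5). Of 17 stem and progenitor genes 8 fell and 2 rose (median -0.33, camera adjusted p = 0.112), and the list passed, downward, with the locus sum (adjusted p = 0.00152) and with library totals (adjusted p = 0.0315), with an adjusted p = 0.0909 and 0.298 with an estimated correlation in these settings. With loess offsets its median was -0.09 (adjusted p = 0.465). CD38 fell by 0.66 ± 0.06, and MSI2 and NRIP1 rose by 0.57 ± 0.08 and 0.25 ± 0.04 at their ends although the locus sums were -0.09 and -0.08. Of 21 lysosomal and phagocytosis genes 8 rose and 3 fell (camera adjusted p = 0.112), with the lysosomal regulator TFEB at 0.38 ± 0.04 and CTSZ at -0.13 ± 0.04, calls that ended over intervals of 1 gene only (0.060) and with library totals (-0.0020). The call of CTSZ ended also with 2.5 kb windows (-0.069) and the locus sum (-0.0011). Homeobox genes of the HOXB, HOXC and HOXD clusters had 6 of 21 down and 3 up (camera adjusted p = 0.265), with HOXD11 at -1.34 ± 0.09, HOXD1 at -1.21 ± 0.21 and HOXC4 and HOXC5, which share their interval, at 0.24 ± 0.05, a call that ended with the locus sum (0.030 and 0.051). With 2.5 kb windows HOXC5 turned to -0.11. Of 16 granulocyte genes 4 fell and 2 rose, or 1 adjusted over the list alone (camera adjusted p = 0.426). PRTN3 was at -0.16 ± 0.05 (not past with library totals, -0.038, 2.5 kb windows, -0.064, or the locus sum, -0.022), MPO at 0.17 ± 0.06 (500 bp windows -0.90) and CSF3R at 0.19 ± 0.08. The call of CSF3R was lost without vehicle 1, 2, 3, 4 or 6 or inhibitor 1, 3, 4 or 5, at values from 0.15 to 0.20. It was also lost with 2.5 kb windows (0.054), RLE factors (0.18), a mean of at least 50 counts (0.17), DESeq2 (0.19), merged near-identical libraries (0.19), 500 bp windows (0.18) and the stronger gene end only (0.18).

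Cell cycle and DNA replication genes had 8 of 26 down and 2 up (camera adjusted p = 0.463), with a median of 0.00, a mean of -0.03 and a downward direction, and passed downward with loess offsets (adjusted p = 0.0428), but not there with an estimated correlation (adjusted p = 0.122). With library totals 15 rose and 3 fell (median 0.13), and with the locus sum 12 rose and 5 fell (median 0.055). The proliferation marker MKI67 fell by 0.42 ± 0.05 and thymidylate synthase, TYMS, by 0.30 ± 0.05, while AURKA had 0.22 ± 0.04 and CDK2 0.15 ± 0.04, the last not past with loess offsets (0.04). Interferon response genes had 9 of 24 up and 4 down (camera adjusted p = 0.463), with IFI6 at 0.52 ± 0.07, STAT2 at 0.24 ± 0.05, IFIT1 at -0.47 ± 0.07 and CXCL10 at -0.80 ± 0.13. The call of STAT2 ended over intervals of 1 gene only (0.045) and that of CXCL10 with the stronger gene end only (-0.21), and IFIT1 turned to 0.069 with the locus sum. FLT3 and cytokine receptor signalling genes had 4 of 21 up and 4 down (camera adjusted p = 0.957), or 13 up and 3 down with library totals (median 0.16), with SOCS1, a feedback inhibitor of cytokine signalling, at 0.60 ± 0.05, IL6R at 0.27 ± 0.04 and the kinase gene PIM2 at -0.45 ± 0.04, a call that ended over intervals of 1 gene only (-0.01).

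Peaks found in only 1 group were more often peaks of vehicle libraries. There were 1639 intervals with a peak in all 6 vehicle libraries and no inhibitor library, and 483 of the opposite kind, 2122 together. No other split of the 12 libraries into groups of 6 gave more than 225. Among peaks with a -log10 q of at least 5 the counts were 803 and 511. Peaks were found in all 12 libraries at 101300 intervals (37.2%) and in a single library at 61349 (22.5%). The number of peaks per library was 173233 ± 8083 (SD, n = 4) with vehicle and 156385 ± 12860 (SD, n = 5) with inhibitor (exact permutation p = 0.0346, adjusted p = 0.0736). Among peaks with a -log10 q of at least 5 the number was 103014 (n = 4) with vehicle and 104861 (n = 5) with inhibitor. Over all 12 libraries the difference was -1229 (exact permutation p = 0.896), so its direction depended on how near-identical libraries were counted. Median peak width was 247.5 ± 6.35 bp and 261.6 ± 12.7 bp (exact permutation p = 0.0368, adjusted p = 0.0736), and the covered length 58.6 ± 3.96 and 56.2 ± 7.14 Mb (exact permutation p = 0.452). None of these 3 measures passed after adjustment, although the number of peaks did without inhibitor 1 (difference -20208.5) and the width without inhibitor 6 (difference 17.7 bp).

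The share of counts per chromosome differed slightly between the groups. It passed an adjusted p of 0.05 for 17 of 23 chromosomes, 6 higher and 11 lower with inhibitor. Shares of a library add up to its whole, so a rise on some chromosomes forces falls on others. Whether the differences follow from the rise of strong intervals and gene ends was not tested. Chromosome 17 went from 5.23% ± 0.0242 (SD, n = 4) to 5.50% ± 0.0817 (SD, n = 5), and chromosome 19 from 8.21% ± 0.0174 to 8.59% ± 0.111. Between the group means over all 12 libraries, which the test used, the relative changes were 5.35% and 5.03% (exact permutation adjusted p = 0.00453 for each). On the same basis chromosome 21 changed by -4.38%, chromosome 4 by -4.11% and chromosome 18 by -4.05%, with the same adjusted p.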

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

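All tests of explanations in this part, the comparison with random loci among them, were chosen after the results had been seen.

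Across both groups of 6 libraries, 206 combinations of a measure and a group were searched. Of the chromosome shares, only that of chromosome 8 was among these measures. A library was flagged where its gap to the nearest other was too large a share of the group's range by Dixon's 95% critical value. There were 18 such values, where chance gives about 1 in 20. Vehicle 2 accounts for 6 of them. It had 6.402% of its counts on chromosome 8 (others 5.962% to 6.058%), 56.78% in the strongest 10% of intervals (others 59.43% to 60.05%), 0.4227% on unplaced contigs (others 0.2184% to 0.2609%), -88 on the first principal component (others -84.61 to -83.37), -57.97 on the third (others -4.903 to 26.53), and 5.703 log2 CPM at PMAIP1 (others 5.866 to 5.941). On chromosomes left out of the search, vehicle 2 also had 1.9382% on X (others 2.0314% to 2.0628%) and 1.1688% on chromosome 21 (others 1.1395% to 1.147%). Inhibitor 5, the library with the fewest counts, accounts for 9 of the 18 values. It had 70.9 on the second component (others -25.45 to -9.366), and its log2 CPM was 1.206 at VPREB1 (others 0.5055 to 0.724), 4.836 at FLT3 (4.992 to 5.077), 4.769 at CASP8 (4.531 to 4.616), 5.899 at AURKA (5.581 to 5.691), 4.005 at KLF1 (3.555 to 3.711), 3.286 at MSI2 (3.736 to 3.947), 4.807 at RBBP5 (4.669 to 4.718) and 0.216 at LGALS3 (1.001 to 1.191). The others were inhibitor 4 at ITGA2B (3.918, others 3.614 to 3.696), vehicle 6 at PRTN3 (4.969, others 4.85 to 4.888) and vehicle 4 at the METTL15 interval (2.316, others 2.683 to 2.883).

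Inhibitor libraries put more of their counts into the strongest intervals, and strong intervals tended to rise. Sequencing depth is argued against, since the lowest inhibitor share exceeded the highest vehicle share by 2.33 percentage points while library totals overlapped. Offsets that remove the trend with abundance kept 82.7% of the interval calls in the same direction, so the trend is not the whole source of the calls. An effect of treatment and a difference in library preparation that went with the group cannot be told apart (exact permutation p of the share = 0.00216), because no label gives a batch within the groups. GC content was not tested, since no genome sequence was at hand, and stays open.

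Menin and KMT2A fusion target loci fell away from their gene ends. Over 20 loci with 526 intervals, 278 fell and 62 rose, and the median over loci was -0.32 against -0.12 to 0.09 in 95% of random draws of matched loci (permutation p = 2e-04, the smallest the draws can give, adjusted p = 0.0028 over 14 lists). The trend with abundance is argued against as the whole cause by a median of -0.28 with loess offsets (random -0.08 to 0.12), and a few loci by a median of -0.22 without the 3 most negative, ARID2, CPEB2 and MEIS1 (random -0.13 to 0.11). A loss of regulatory elements within or near target genes after menin inhibition is a candidate explanation that was not tested. GC content and a difference in preparation between the groups stay open.

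MHC class II and antigen presentation genes rose. Fragments shared between near-identical HLA genes are argued against as the whole cause of the list's rise by the 6 members outside the HLA genes, of which 5 rose (median 0.30, against 0.76 for the 12 HLA members). These 6 cannot show whether fragments were misplaced among the HLA genes, so for the HLA members the question stays open. The trend with abundance is argued against by a list median of 0.54 with loess offsets. Induction by the inhibitor may explain the rise. B cells in the treated wells are argued against by the design. All wells were seeded with an established line from an expanded culture, and the labels name no source of B cells. The markers of B cells could not decide it alone. Of 12 tested, 0 rose and 4 fell in edgeR (median -0.064), while with library totals 2 rose and 3 fell (median 0.065), with loess offsets 1 rose and 3 fell, and with locus sums 3 of 15 rose and 6 fell. The signal of the line itself at these markers could hide a small share of B cells. GC content and a preparation difference stay open.

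Chance assignment of libraries to groups was tested on 100 splits of the 12 libraries, the real one included. Only 1 split, the real one, gave as many changed intervals (5242 of 10000 sampled, highest other 1751), as many changed gene ends (8059, highest other 2809) or as many lists (10, highest other 8). For lists the margin was narrow. Mixed splits carry the group difference as spread within their groups, which lowers their counts. The splits also cannot address wells that may be technical repeats of 1 culture.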

How the results depend on the processing

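Merging near-identical libraries and using the stronger gene end only were chosen after the data had been seen. The corrections for GC content, alone and with the replicate block, and the motif settings were not run. The 16 named intervals kept direction and side of the threshold under every setting run on them. Leaving out each library gave 95665 to 102826 changed intervals, 7533 to 8459 gene ends, 10 lists, 17 chromosomes, a difference of 3.99 to 4.74 points in the strongest 10% of intervals, 1771 to 2346 vehicle-only and 502 to 644 inhibitor-only intervals. Of 912 gene values without 1 library, 882 kept their call, 27 lost and 3 gained it. Libraries with the same replicate number had nearly uncorrelated deviations from their group means (-0.013 to 0.051). For 2 of 6 numbers, replicates 2 and 3, they were still each other's best match across the groups. As a block the replicate numbers gave 100601 intervals, 8550 gene ends and 10 lists.

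A mean of at least 50 counts, which tests fewer intervals, gave 47452 changed intervals (23350 higher, 24102 lower), and a 2-fold threshold 15825 intervals and 340 gene ends. Intervals at least 2-fold higher numbered 2639 with library totals, 6965 without a filter, 611 with a mean of at least 50 and 6347 with DESeq2. Those 2-fold lower numbered 21501 without a filter, 2582 with a mean of at least 50 and 21575 with DESeq2. Locus sums, which hold more counts, gave 12422 changed genes (6552 higher, 5870 lower). Of the 8059 gene-end calls, locus sums kept 5736 in the same direction and reversed 525. Loess offsets kept 5771 of them and reversed 0. Library totals, which let the gene-end median move from 0.01 to 0.14, gave 7837 higher and 2070 lower. Gene ends 2-fold higher were 45 with library totals, 60 with loess offsets and 12 with locus sums. Those 2-fold lower were 205, 112 and 201 with the same settings, 521 without a filter, 94 with a mean of at least 50 and 534 with DESeq2. For these differences the cause was not tested beyond the construction named.

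With an estimated correlation 4 lists passed and with fry, which tests each list on its own, 16. The direction of 6 lists that did not pass reversed, at these adjusted p: cell cycle 0.669 with library totals and 0.433 with locus sums, epithelial and fibroblast 0.333 and FLT3 signalling 0.565 and HOXB to HOXD 0.701 with loess offsets, and erythroid 0.636 and granulocyte 0.499 with locus sums. Without 1 library, epithelial and fibroblast markers reversed at 0.912 (without vehicle 2) and 0.962 (inhibitor 3), and FLT3 signalling at 0.977 (vehicle 1), 0.912 (vehicle 2) and 0.993 (inhibitor 3). Over the leave-one-out settings the adjusted p ran from 0.770 (without vehicle 1) to 0.962 and from 0.822 (without vehicle 3) to 0.994 (without inhibitor 1). The cause was not tested.

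The odds ratio of rises at gene ends was 0.483 among 2-fold calls and 1.51 with loess offsets, and that of falls 0.252 and 0.591. Over all 12 libraries, peaks with a -log10 q of at least 5 gave differences of 0.805 Mb in covered length and -1229 in peak number. With near-identical libraries counted once, the mean peak number was 103014 with vehicle and 104861 with inhibitor, the other direction. These peaks gave 803 vehicle-only and 511 inhibitor-only intervals. A rule of at least 5 of 6 against at most 1 of 6, which is looser, gave 6631 and 2378. Over intervals that did not pass on their own, 0 chromosomes differed, before or after adjustment of the exact permutation p, an outcome that choosing intervals by their change largely fixes. The difference in peak number was -20208.5 to -14081.3 without 1 library, past the threshold without inhibitor 1 (adjusted p = 0.0325), and in width 10.9 to 17.7 bp, past it without inhibitor 6 (adjusted p = 0.0260).

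With locus sums, which add intervals away from the ends, the log2 fold change became 0.073 for FCER2, 0.17 for NKG7, 0.10 for EPOR, -0.0875 for MSI2, -0.0753 for NRIP1, 0.035 for RPS18, 0.069 for IFIT1, -0.49 for JMJD1C, 0.036 for RBBP5 and 0.0102 for ITGAM. With 2.5 kb windows it was 0.042 for EPOR, -0.11 for HOXC5 and -0.21 for JMJD1C, with 500 bp windows -0.90 for MPO, and over intervals of 1 gene only -0.37 for JMJD1C. With library totals it was 0.047 for RPS18, 0.021 for AFF1 and 0.036 for PBX3, and with the stronger gene end only 0.13 for RPS18. Beyond the construction named, the cause was not tested. In simulated data with only 200 changed features, which do not test the scaling, 33 of 67 changes of 1.5-fold were recovered for intervals and 63 of 67 for gene ends.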

Other observations

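The tests in this part, and the genes named in it, were chosen after the values had been seen.

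Away from gene ends, the call for monocyte and macrophage loci depended on the scale. Over 13 loci with 111 intervals, 60 rose and 17 fell, with a median over loci of 0.23 against -0.09 to 0.19 for random loci (adjusted p = 0.0574 over 14 lists). With loess offsets the median was 0.25 (random -0.11 to 0.14, adjusted p = 0.0014, from the smallest p the draws can give).

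Among 3757 windows of 500 kb with at least 20 tested intervals, the lowest median log2 fold change was -1.09. It belonged to a window over CWH43 (chromosome 4, 49000001 to 49500000), where only 3 of 21 intervals passed as lower. The next lowest, a window that overlaps part of MEIS1 (chromosome 2, 66500001 to 67000000), had -0.82, with 17 of 22 intervals lower. Windows over UGCG, FAT3 and MYT1L followed, with -0.78, -0.75 and -0.74. Windows over SATB1 (chromosome 3, 18000001 to 18500000) and PARP8 (chromosome 5, 50500001 to 51000000) had -0.72 (44 of 66 lower) and -0.67 (52 of 82 lower), with other windows between them in rank. The highest medians, 0.62, 0.60 and 0.55, belonged to windows over PDE1C, PID1 and PRUNE2. Next in rank were windows over HLA class II genes (chromosome 6, 32500001 to 33000000), TET2 (chromosome 4, 105000001 to 105500000) and KLF6 (chromosome 10, 3500001 to 4000000), with 0.53, 0.49 and 0.47.

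At gene ends, values far from the rest included SGK1 (2.47 ± 0.10), CXCL8 (2.41 ± 0.05, from 8.29 to 43.5 CPM), CXCL11 (1.54 ± 0.11), SCG5 (-2.71 ± 0.12) and SH3GL2 (-2.83 ± 0.08, from 17.4 to 2.63 CPM). Falls of at least 2-fold were more frequent (312) than such rises (28). Of 104 families of genes sharing the leading letters of their symbol, 9 passed with camera, and 2 of these with an estimated correlation too. The 2 were CFAP genes of cilia and flagella, with 26 of 44 down and 2 up (camera adjusted p = 3.63e-06), and SPATA genes, with 12 of 22 down and 0 up (camera adjusted p = 6.55e-04), each having an adjusted p = 0.0452 with an estimated correlation. HLA genes had the smallest camera adjusted p, 4.47e-09 (14 of 16 up, 1 down), and an adjusted p = 0.0961 with an estimated correlation. The families were tested with TMM factors only and not with loess offsets. Whether the trend of strong intervals to rise and weak ones to fall accounts for the family calls was therefore not tested.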
